A study of Mus musculus with 16 samples.

How the data were processed

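RNA was profiled in pericytes and endothelial cells sorted by flow cytometry from primary mouse mammary tumours of wild-type and endosialin-knockout hosts. Per the labels' protocols, 67NR tumour cells were placed in the mammary fat pad of female BALB/c Ub-GFP mice aged 6 to 8 weeks, and tumours grew for 2 to 4 weeks to a mean diameter of 10 mm. Sorted cells were used without culture. Their RNA was amplified with the Ovation Pico WTA System V2, and 1.6 µg of labelled cRNA was hybridised to Illumina MouseWG-6 v2.0 bead arrays. The gate markers, the number of mice or tumours behind each array, and the chip and date of each array are not given in the sources used here.

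The deposited table holds normalized probe intensities on a log2 scale, which the authors made with GenomeStudio and lumi per the submitters' processing notes. Their versions, the background correction, the transform (a plain log2 or the log2-like variance-stabilizing transform of lumi), the method between arrays and any probe filter are not given in the sources used here. The deposited values were used as they are. They cover 24040 probes on 16 arrays, and the table holds 0 columns of samples outside the series. The repository's own value table differed from it by at most 5.00e-09. Array medians lay between 7.18 and 7.21. The lowest value was 6.58 and lower quartiles lay between 6.92 and 6.96, so the scale is compressed near its floor and folds of dim transcripts are understated. The number of arrays limits the precision.

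A probe was kept when its value lay above the median of its array on at least 4 of the 16 arrays, as no detection p-values are given. This kept 14632 probes. A gene with several kept probes, which applied to 2904 genes, was represented by the probe with the highest mean over all arrays, giving 10426 genes. Symbols are those of the array annotation. For current names and chromosome neighbours, the genes were matched to the RefSeq table of the mouse assembly GRCm38.p6: 7554 matched by accession, 491 by symbol and 653 by synonym, 8698 in all, and 1728 (16.6%) were not matched. The files name no genome build, and no coordinates are given.

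Arrays were grouped by the labels into wild-type pericytes, knockout pericytes, wild-type endothelial cells and knockout endothelial cells, 4 arrays each. A group-means model was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3, with moderated two-sided tests, 12 residual and 5.58 prior degrees of freedom, and Benjamini-Hochberg adjustment over the 10426 genes at a threshold of 0.05. There were 5 contrasts: knockout against wild type in pericytes and in endothelial cells, the difference between these effects, and pericytes against endothelial cells in each genotype. Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, with camera at an estimated correlation and fry beside it. Of 31 lists with tested members, the 25 with at least 5 were tested as sets. They cover markers of pericytes, smooth muscle, endothelium, lymphatic endothelium, fibroblasts, macrophages and granulocytes, lymphocytes, epithelial tumour cells, adipocytes, erythroid cells and Schwann cells. The others cover MHC class II, interstitial matrix, basement membrane, matrix proteases and inhibitors, angiogenic tip cells, Notch and arterial genes, leukocyte adhesion, endothelial junctions, the TGF-beta and BMP response, PDGF and pericyte recruitment, and hypoxia. They also cover the cell cycle, the interferon response, inflammatory cytokines, immediate early genes, heat shock, oxidative phosphorylation, cytosolic ribosomal proteins, endosialin ligands with C-type lectin relatives, and the neighbours of Cd248 on chromosome 19. A list of skeletal muscle genes had 0 tested members. Separate lists of keratinocyte, mast cell, luminal epithelial and neutrophil markers were written after the first calls were seen.

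The rule for named genes, fixed at the same time as those lists, took Cd248 first. It then took the 10 genes with the largest change in each direction among those past the threshold whose arrays of one group all lay above those of the other, leaving out symbols with no established name. Where fewer than 10 passed, it took all that passed and the 5 with the smallest unadjusted p in each direction. It added up to 4 members of each list described, and 8 genes that identify the sort.

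On simulated data with the same layout, limma recovered 62.7% of true changes of 0.5 log2 in pericytes, 68.7% in endothelial cells, 22.4% for the difference of effects, and 64.2% and 58.2% for the cell type comparisons in wild type and knockout. For changes of 1 log2 the shares were 100%, 94.0%, 85.1%, 94.0% and 98.5% in the same order, and for 2 log2 they were 100%, 98.5%, 98.5%, 100% and 100%. Wrong calls among unchanged genes numbered 8, 7, 7, 8 and 5. The simulated noise was independent between genes and had the same SD in every group. These shares therefore do not carry over to genes that vary together or whose spread differs between groups.

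Alternatives covered the probe filter (none or stricter), the choice of probe, normalization (quantile again or median centring), the repository's table, a floor at the 25th percentile, replicate blocks, the groups in the fit, the variance model with statmod 1.5.0, array weights, a size threshold of log2 1 and leaving out each array. With 2 alternatives added after seeing the data, the keratinocyte marker mean entered as a covariate or the 3 knockout pericyte arrays with most keratinocyte transcripts were left out. A block for the chip could not be run, since no chip is named. Figures were drawn with matplotlib 3.10.9. No sample was left out of the comparisons.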

Results

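Whole-genome bead arrays measured transcripts in tumour pericytes and tumour endothelial cells sorted from 67NR tumours, a mouse mammary carcinoma line grown in the mammary fat pad. The hosts were wild type or lacked endosialin (Cd248), a C-type lectin-like membrane glycoprotein of pericytes and fibroblasts. There were 4 groups of 4 arrays each. After the authors' normalization signal was even between arrays, with median log2 intensities from 7.18 to 7.21 and values up to 14.5. Correlation across genes was 0.916 to 0.979 between arrays of 1 group, 0.917 to 0.981 between genotypes of 1 cell type, and 0.695 to 0.784 between cell types. The first principal component held 74.8% of the variance and parted the cell types. The second held 5.73% and placed knockout pericyte replicates 2, 3 and 4 at 15.95, 13.5 and 12.9, while knockout replicate 1 lay at -11.2 and the wild-type pericytes between -15.8 and 1.04. All p-values measure only the spread between these samples, since the labels do not state whether the replicates are separate animals.

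Cd248 was abundant in wild-type pericytes and low in every other group, at or below 7.44 where array medians lay between 7.18 and 7.21. Its probe with the higher mean (ILMN_2896843) read 11.19, 10.75, 10.85 and 11.12 in the wild-type pericyte arrays and 7.21, 7.10, 7.09 and 6.96 in the knockout pericyte arrays. Wild-type endothelial arrays read 6.96, 6.92, 6.94 and 7.33, and knockout endothelial arrays 7.44, 7.36, 7.04 and 7.23. In pericytes the log2 mean fell from 10.98 ± 0.21 to 7.09 ± 0.10 (SD, n = 4 each), a 14.8-fold loss with a log2 difference of -3.89 (SE 0.12, limma, Benjamini-Hochberg adjusted p = 4.20e-13). The other probe (ILMN_2670001) fell from 8.55 ± 0.44 to 6.71 ± 0.01 (SD, n = 4 each), 3.57-fold (limma, adjusted p = 1.52e-06). In endothelial cells the values were 7.04 ± 0.20 in wild type and 7.27 ± 0.18 in knockout (SD, n = 4 each), a difference of 0.23 that did not pass (limma, adjusted p = 1).

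**Figure D1:**
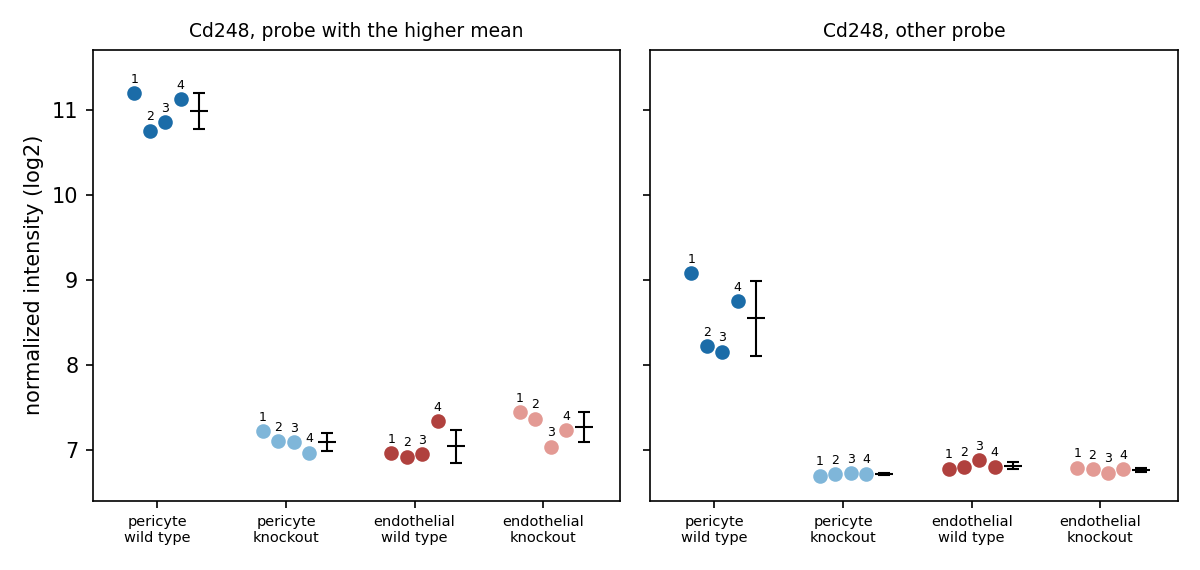
Normalized log2 intensity of both Cd248 probes in every array, by group, with replicate numbers and bars for the mean and SD of 4 arrays. On the left probe the wild-type pericyte arrays lie between 10.75 and 11.19, and all other arrays lie at or below 7.44.

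The comparison of knockout with wild-type pericytes asks how loss of endosialin changes the cells that carry it. Apart from the loss of Cd248, 32 genes were higher in knockout pericytes. Of them 13 are on a list of keratinocyte markers that was written after the first calls were seen. The basal keratinocyte keratins Krt5 and Krt14 rose 9.25-fold and 7.23-fold. The cysteine protease inhibitors of the stefin A family, Stfa1 and Stfa3, rose 5.96-fold and 3.08-fold. Osbp, a sterol-binding lipid transfer protein, rose 1.48-fold, and its 4 knockout arrays all lay above its 4 wild-type arrays. No gene other than Cd248 fell past the threshold.

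Krt5 rose from 7.91 ± 0.92 to 11.12 ± 1.36 (SD, n = 4 each; limma, adjusted p = 0.00824) and Krt14 from 7.87 ± 1.10 to 10.72 ± 1.17 (SD, n = 4 each; limma, adjusted p = 0.0129). The keratins Krt6b and Krt16, which mark hair follicles and activated epidermis, rose by 2.34 and 2.13 on the log2 scale (limma, adjusted p = 0.0306 and 0.043). Other genes that rose were Krtdap by 1.91, the glycerol channel Aqp3 by 1.96, Trim29 by 1.67, stratifin (Sfn) by 1.05 and suprabasin (Sbsn) by 0.67. The desmosomal Perp rose by 1.78 and Dsp by 1.64, the hemidesmosomal collagen Col17a1 by 1.55 and the anchoring fibril collagen Col7a1 by 0.58, while the desmosomal Pkp3 did not pass (limma, adjusted p = 0.170). Within the stefin A cluster, Stfa1 rose by 2.58, BC100530 by 2.03, BC117090 by 1.89, Stfa3 by 1.62 and EG433016 by 1.22. The transcription factor gene Tcfap2c rose by 1.77 and the mitochondrial creatine kinase Ckmt1 by 1.57. The fatty acid carrier Fabp5 rose by 0.69, the glycolipid transfer protein Gltp by 0.61 and the syndecan Sdc4 by 0.43. Adjusted p of these genes lay between 0.00375 for Stfa3 and 0.0484 for Tcfap2c (limma). Osbp rose from 7.60 ± 0.07 to 8.16 ± 0.15 (SD, n = 4 each; limma, adjusted p = 0.00824), and the unnamed transcript LOC100042514 rose from 7.11 ± 0.43 to 8.46 ± 0.18 (limma, adjusted p = 2.72e-04). Krt6b, Krt16, Krtdap, Aqp3, Perp, Dsp, Col17a1, Stfa1, BC100530, BC117090, EG433016, Tcfap2c, Ckmt1, Sdc4 and LOC100042514 were chosen after their values were seen.

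These transcripts were unevenly spread over the knockout pericyte arrays. The mean over 21 keratinocyte markers, a list written after the first calls were seen, was 9.64, 9.55 and 9.19 in knockout replicates 2, 3 and 4, against 7.41 in knockout replicate 1. The wild-type pericyte arrays read 7.02, 6.95, 7.75 and 7.25, and the endothelial arrays 6.85 to 7.02. Of this list 13 members rose in knockout pericytes and all 21 had a positive difference, with a median of 1.72. Those 13 are among the 32 genes higher in the knockout. Of the 21 members, 1 lay above the array median on every wild-type pericyte array and 11 on every knockout pericyte array. The probe filter could thus keep a gene through its high knockout arrays, which favours positive differences. Mast cell markers and Cd3e, a CD3 subunit of the T cell receptor complex, were also lowest in knockout replicate 1 among the knockout pericyte arrays. The mast cell marker mean was 7.25, 8.83, 9.56 and 8.78 in knockout replicates 1 to 4, and Cd3e stood at 8.03, 9.69, 9.46 and 8.82. In wild-type pericytes, where the keratinocyte mean stayed at or below 7.75, the mast cell mean reached 9.86 in replicate 4, with Cd3e at 8.76. S100a9, a granulocyte calprotectin gene also made by stressed epidermis, followed the same arrays, at 9.10, 8.88 and 9.65 in knockout replicates 2 to 4 against 6.75 in replicate 1, and did not pass (1.54, limma, adjusted p = 0.139). The luminal keratins Krt8 and Krt18 each differed by 0.38 and did not pass, with their highest values, 8.56 and 8.98, in knockout replicate 4.

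**Figure D2:**
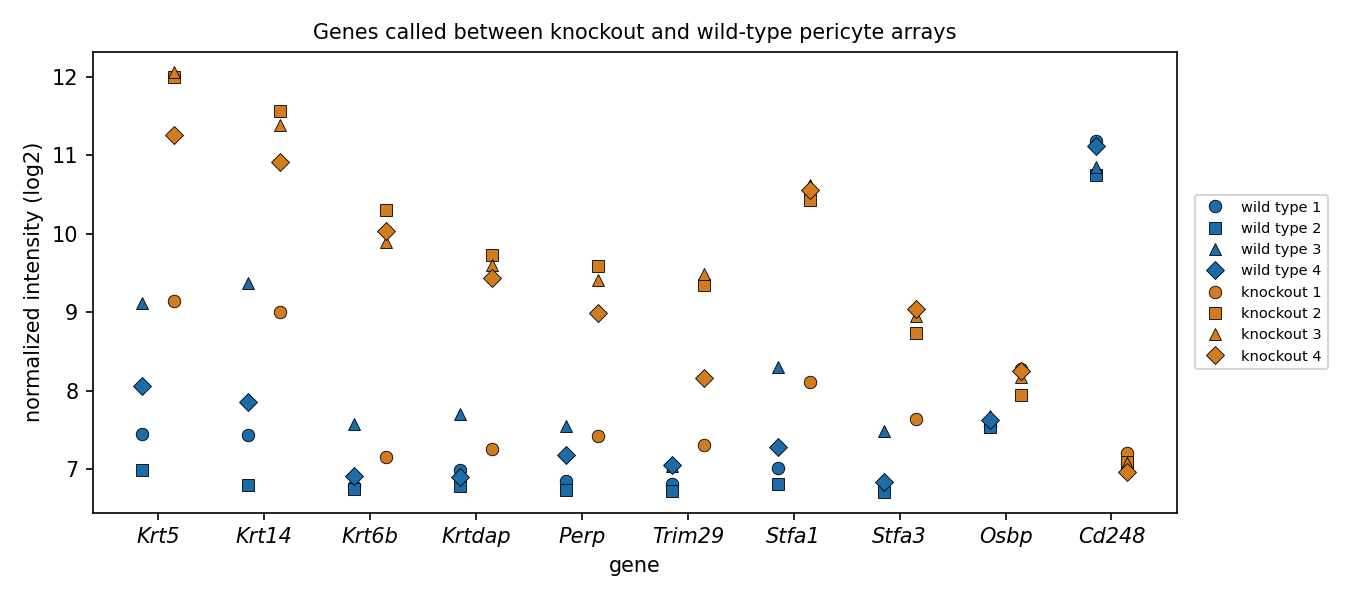
Normalized log2 intensity of 10 genes called between knockout and wild-type pericytes, with 1 symbol per array, blue for wild type and orange for knockout. For Krt5 and Krt14 knockout replicates 2 to 4 lie above 10.9 and knockout replicate 1 lies near 9.15 and 9.01. Osbp, Cd248, Trim29, Stfa3 and Krt5 part the genotypes in every array, and the other genes shown do not. Krt5 does so narrowly, with its lowest knockout array at 9.15 and its highest wild-type array at 9.12.

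Among the fixed lists, epithelial tumour cell markers were higher in knockout pericytes. All 9 tested members had a positive difference, with a median of 1.18. Of them Krt5 and Krt14 rose over all genes tested and 7 rose when adjusted over the list alone (camera, adjusted p = 3.23e-15, and adjusted p = 0.148 with an estimated correlation). Interstitial matrix genes had a median of -0.12, with 0 of 23 members passing and Col5a2 at -0.28 (camera, adjusted p = 0.0372, and adjusted p = 0.867 with an estimated correlation). Endosialin ligands and C-type lectin relatives also had a median of -0.12, with 0 of 8 passing, Lgals3bp at -0.34 and Col4a1 at -0.19 (camera, adjusted p = 0.0434, and adjusted p = 0.224 with an estimated correlation). Interferon response genes had a median of -0.12 with 0 of 18 passing, Zbp1 at -0.61 and Usp18 at -0.25 (camera, adjusted p = 0.0449, and adjusted p = 0.867 with an estimated correlation). The mean of the 2 MHC class II genes was 7.49 ± 0.73 in wild-type and 7.09 ± 0.15 in knockout pericytes (SD, n = 4 each), and neither gene passed. In the TGF-beta and BMP list 1 of 21 members rose, Tgfbi, a matrix protein induced by TGF-beta, by 0.83 (limma, adjusted p = 0.014). Its deviations from group means followed those of Krt5 and Krt14 over the pericyte arrays (r of 0.89), and with the keratinocyte mean as a covariate it stood at 0.38 (limma, adjusted p = 1.00). None of the 18 pericyte markers passed, and their median was -0.13 (camera, adjusted p = 0.105), with Pdgfrb at -0.16 and Rgs5 at -0.32. Adjusted over the list alone, S100a9 rose among macrophage and granulocyte markers, Mmp10 (0.51) among matrix proteases, and Gja1 (0.41) and Pkp4 (0.42) among junction genes, while Il11 fell by 0.44 among cytokines. The macrophage and granulocyte list as a whole did not rise with S100a9, with a mean of 7.59 ± 0.59 in wild-type and 7.56 ± 0.45 in knockout pericytes (SD, n = 4 each). None of these passed over all genes, with limma adjusted p of 0.103 for Mmp10, 0.252 for Gja1, 0.40 for Pkp4 and 0.140 for Il11. The heparin-binding growth factor Hbegf differed by 0.85 and did not pass (limma, adjusted p = 0.408). With the keratinocyte mean as a covariate, differences turned to -0.15 for Hbegf, -0.03 for Pkp4, -0.23 for S100a9 and 0.03 for Col5a2. Mmp10, Gja1, Il11, Lgals3bp, Col4a1, Zbp1, Usp18, Pdgfrb and Rgs5 kept their direction.

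In all, 33 of 10426 genes passed in pericytes (limma, Benjamini-Hochberg threshold 0.05), 23 of them by 2-fold or more, and 743 had an unadjusted p under 0.05 against 521.3 expected by chance. Over all genes, 314 (3.01%) had pericyte arrays fully parted by genotype in either direction, where chance alone gives 2.86%. They include 16 of the 32 higher genes, which were picked by their difference. Only Cd248 passed when the fit held the pericyte arrays alone or when the keratinocyte mean was a covariate. The count fell to 14 with no filter, 5 with a stricter filter and 16 with a trended robust variance, and rose to 96 with array weights. Another fit left out knockout replicates 2 to 4, which were picked by their high keratinocyte mean. This lowers keratinocyte genes by construction and leaves 1 knockout pericyte array. There 25 of the 32 higher genes kept less than 0.5 of their size. With the pericyte arrays alone the differences are the same by construction and the SE rose by a median factor of 1.31. With the covariate, whose 21 genes include 13 of the 32, 26 kept less than 0.5 of their size, as Krt6b did, going from 2.34 (SE 0.45) to 0.04 (SE 0.18). Within a factor of 1.5 stayed 5 genes, among them Sdc4 with 0.43 (SE 0.08) before and 0.44 (SE 0.13) after, Col7a1 with 0.58 (SE 0.11) and 0.48 (SE 0.18) and Osbp with 0.56 (SE 0.09) and 0.68 (SE 0.14), where the SE grew. Leaving out 1 array gave 130 genes without knockout pericyte replicate 1, 4, 3 and 17 without replicates 2, 3 and 4, and 13, 8 and 12 without wild-type pericyte replicates 1, 2 and 4, and it gave 15 without wild-type endothelial replicate 4 and 12, 15 and 15 without knockout endothelial replicates 1, 3 and 4.

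**Figure D3:**
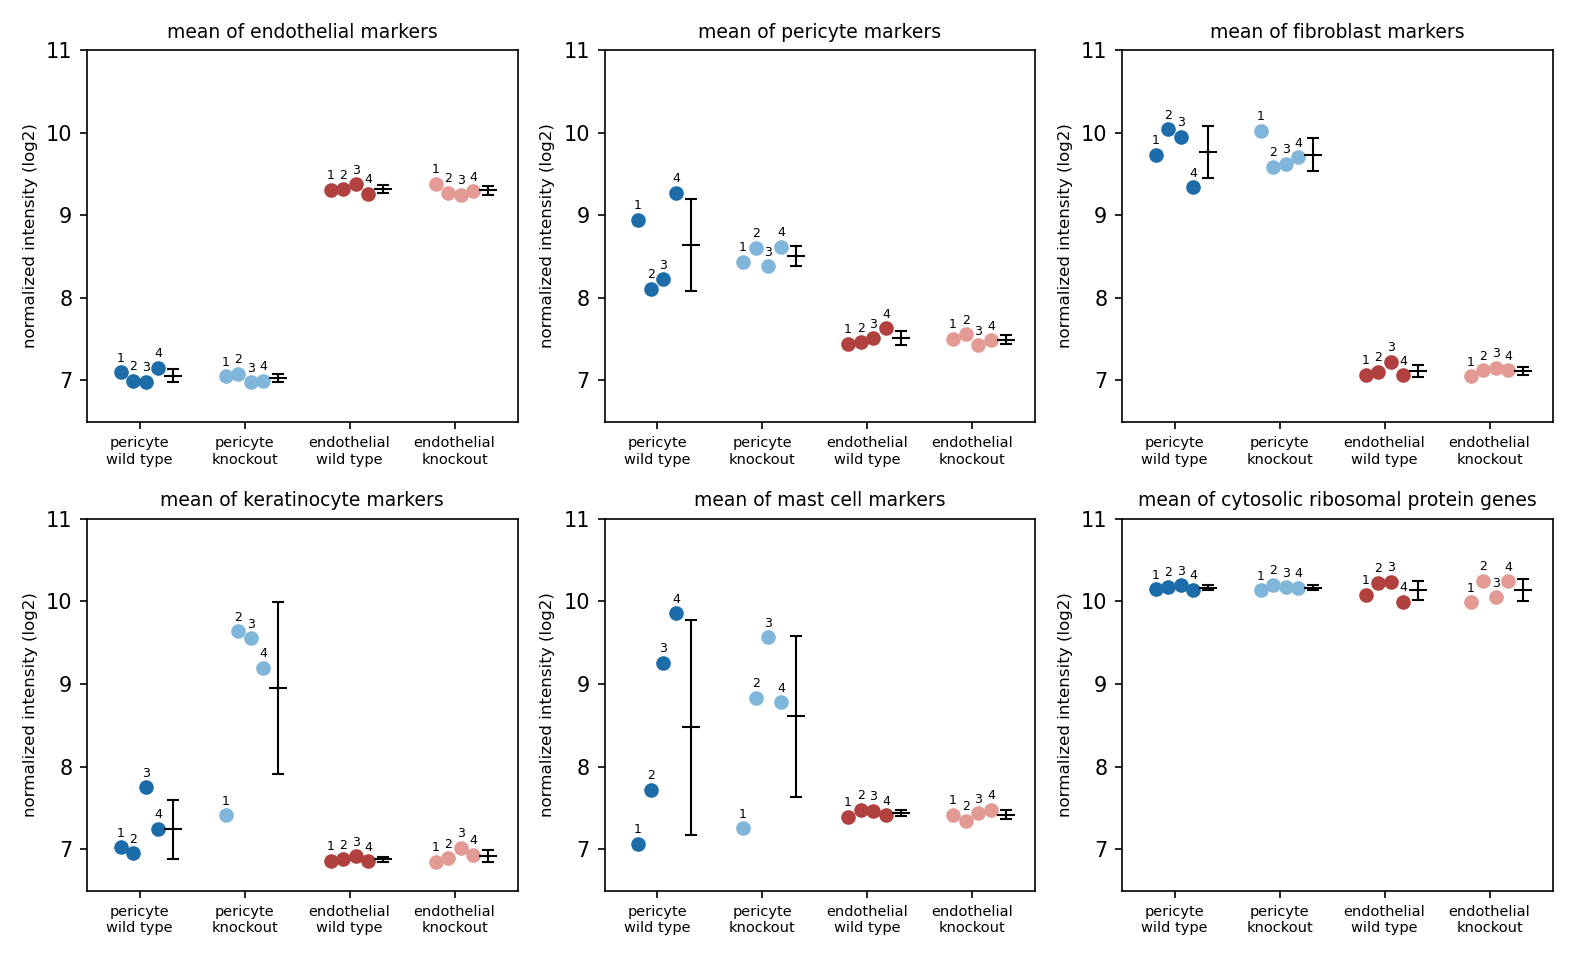
Mean normalized log2 intensity over the tested members of 6 gene lists in every array, by group, with replicate numbers and bars for the mean and SD of 4 arrays. Endothelial, pericyte and fibroblast markers part the cell types, and keratinocyte markers reach 9.19 to 9.64 in knockout pericyte replicates 2 to 4 against at most 7.75 in the other arrays.

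In endothelial cells, where Cd248 was low in both genotypes, knockout and wild-type hosts were compared to ask whether loss of endosialin in the surrounding cells changes the vessel lining. Osbp, read by 1 kept probe, was the 1 gene that passed. It rose from 7.63 ± 0.11 to 8.34 ± 0.07 (SD, n = 4 each), 1.64-fold, with all 4 knockout arrays above all 4 wild-type arrays (log2 difference 0.71, SE 0.09, limma, adjusted p = 0.0019). Osbp was also the 1 gene called in both cell types. Across genes the knockout differences of the cell types had a correlation of 0.19, where genes are not independent replicates.

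The next endothelial genes by unadjusted p did not pass. Higher in knockout were the lens crystallin gene Cryba1 by 0.68 (limma, adjusted p = 0.560), the cytokine signal transducer Stat5a by 0.51, Gt(ROSA)26asSor by 0.51, the mitochondrial ribosomal protein gene Mrpl12 by 0.38 and the acetyltransferase Kat5 by 0.30. Lower values were found for the short-chain acyl-CoA dehydrogenase Acads (-0.80, limma, adjusted p = 0.560), Mov10 (-0.39), Mfap1b (-0.38), Cdc42se2 (-0.32) and Mansc1 (-0.26). Interferon response genes had a median of -0.24, with 17 of 18 members negative and Ifit2 at -0.50, and none passed (camera, adjusted p = 2.29e-04, and adjusted p = 0.985 with an estimated correlation). Camera called no other list, and fry called none. With a replicate block camera also called macrophage and granulocyte markers, which had a median of -0.27 with 5 of 6 members negative and 0 passing (adjusted p = 0.0217, and adjusted p = 0.130 without the block). The 2 MHC class II genes had a median of -0.51 and did not pass. Adjusted over the list alone, the adhesion receptor Icam1 rose (0.66) in the adhesion and the cytokine lists, and the lymphatic receptor Flt4 fell by 0.19. The keratinocyte list had a median of 0.03 in endothelial cells, with 0 of 21 members passing. In all, 387 genes had an unadjusted p under 0.05 (limma), where 521.3 are expected by chance. The count was 2 without wild-type endothelial replicate 2, where Acads fell as well, 2 with array weights or with every probe tested, and 0 with a size threshold of log2 1.

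The test of the difference between these effects asks where the response to the knockout depended on the cell type. Cd248 fell in pericytes and not in endothelial cells, a difference in effect of -4.12 (SE 0.17, limma, adjusted p = 6.11e-11). The effect on LOC100042514 was greater in pericytes by 1.38 (SE 0.21, limma, adjusted p = 0.025). The keratinocyte and stefin genes did not pass this test: Krt5 differed by 3.18 (limma, adjusted p = 0.483), Stfa1 by 2.53, Stfa3 by 1.59 (limma, adjusted p = 0.324), Tgfbi by 0.84 and Col7a1 by 0.65. On the negative side, and not passing, were Ttc19 at -0.64, the histone acetyltransferase Myst3 at -0.55, Cntln at -0.51, the cytokine Il11 at -0.51 and the Toll-like receptor adaptor Myd88 at -0.42. Epithelial tumour cell markers had a median of 1.03 with 0 of 9 passing over all genes and 6 when adjusted over the list alone (camera, adjusted p = 1.31e-10, and adjusted p = 0.415 with an estimated correlation). Tgfbi also passed when adjusted over its list alone. Interstitial matrix genes had a median of -0.14 with 0 of 23 passing (camera, adjusted p = 0.0457, and adjusted p = 0.950 with an estimated correlation). In all, 2 genes passed and 390 had an unadjusted p under 0.05 against 521.3 expected by chance. Cd248 was the 1 gene that passed with no filter, with a stricter filter and with the keratinocyte mean as a covariate. Leaving out any 1 array also left only Cd248, except for wild-type pericyte replicate 3 (2 genes) and knockout pericyte replicate 1 (53 genes). Array weights gave 10.

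Pericytes and endothelial cells of wild-type tumours were compared to ask what sets the sorted populations apart, and the same was done in knockout tumours. In wild type the lists of fibroblast markers, interstitial matrix genes, matrix proteases and inflammatory cytokines were higher in the pericyte sort, and those of endothelial markers, junction genes and tip cell genes were lower. Col3a1 was 33.9-fold higher in pericytes and the chemokine-like Rarres2 26.2-fold. The tight junction gene Cldn5 was 18.6-fold lower and the adhesion receptor Pecam1 13.7-fold lower. In wild type 3772 of 10426 genes differed (limma, Benjamini-Hochberg threshold 0.05), 1785 higher and 1987 lower in pericytes, and in knockout 3743, 1809 higher and 1934 lower. Of these, 1480 were higher and 1531 lower in both genotypes, where independent lists would share 309.7 and 368.6, and 0 were opposite. Counts at 2-fold or more were 920 in wild type and 954 in knockout, and a stricter filter, which tests 5683 genes, gave 2176 and 2034.

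Col3a1 stood at 12.02 ± 0.34 in wild-type pericytes and 6.94 ± 0.11 in wild-type endothelial cells (SD, n = 4 each; limma, adjusted p = 1.16e-14). Log2 differences of the other leading pericyte genes in wild type were 4.71 for Rarres2, 4.38 for the protease inhibitor Serpine2, 4.32 for the proteoglycan Dcn and for Col5a1, 4.21 for Thy1, 4.16 for the proteoglycan Bgn, 4.12 for Cpxm1, 4.09 for Col1a1 and 4.06 for Col6a2. Cd248 itself differed by 3.94 in wild type, 15.4-fold (limma, adjusted p = 1.96e-14), and by -0.18 in knockout (limma, adjusted p = 0.281). In knockout the leading genes were Col3a1 (4.77), Rarres2 (4.64), Dcn (4.26), Krt5 (4.24), Cpxm1 (4.16), Thy1 (4.14), Serpine2 (4.06), Col6a2 (4.06), the stromelysin Mmp3 (3.98) and Col1a1 (3.94). Krt5 in wild type differed by 1.06 and did not pass (limma, adjusted p = 0.101). All 21 keratinocyte markers were higher in pericytes in knockout and 1 in wild type. The pericyte markers Rgs5, Des, Pdgfrb and Cspg4 were higher in pericytes by 3.20, 2.09, 1.33 and 1.18 in wild type and by 2.90, 1.94, 1.14 and 1.06 in knockout. Cspg4 in knockout no longer passed with the keratinocyte mean as a covariate (0.98, limma, adjusted p = 0.187) or without knockout pericyte replicates 2 to 4 (0.91, limma, adjusted p = 0.194). Smooth muscle actin, Acta2, differed by 0.35 and 0.51 and did not pass (limma, adjusted p = 0.286 and 0.117). It passed as the mean of its probes, at 1.37 and 1.32, and without wild-type pericyte replicate 2, at 0.67 and 0.51 (limma, adjusted p = 0.00594 and 0.019). In wild type it also passed with array weights (0.56) and in knockout with only the groups compared (0.51).

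Endothelial genes were lower in pericytes in both genotypes. Cldn5 was 6.83 ± 0.09 in wild-type pericytes and 11.04 ± 0.16 in wild-type endothelial cells (SD, n = 4 each; limma, adjusted p = 3.26e-15). Wild-type differences were -4.07 for the guidance receptor Robo4, -3.88 for Igfbp3, -3.77 for Pecam1, -3.71 for Egfl7, -3.69 for the tip cell proteoglycan Esm1, -3.61 for the lipase anchor Gpihbp1, -3.42 for Cd93, -3.36 for Lmo7 and -3.24 for the endothelial cadherin Cdh5. In knockout they were -4.14 for Robo4, -4.06 for Cldn5, -3.82 for Igfbp3, -3.79 for Egfl7, -3.70 for Esm1, -3.63 for Pecam1, -3.56 for Gpihbp1, -3.39 for Cd93, -3.33 for the peptide hormone Apln and -3.32 for its receptor Aplnr. The VEGF receptor Kdr fell by 0.86 in wild type and by 1.03 in knockout.

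Of the marker lists in wild type, all 25 endothelial markers were lower and all 20 fibroblast markers higher in pericytes (camera, adjusted p = 2.43e-27 and 3.62e-21, and adjusted p = 2.06e-04 and 0.0152 with an estimated correlation). The fibroblast markers included Serpinf1 (3.93) and Fbln1 (3.71). Of 18 pericyte markers 14 were higher and 1 lower, among them Rgs4 (2.20) and the guanylate cyclase subunit Gucy1a3 (1.87), with the same numbers adjusted over the list alone (camera, adjusted p = 1.49e-07, and adjusted p = 0.256 with an estimated correlation). Of 10 smooth muscle genes 5 were higher and 1 lower, with Tpm2 at 2.63, Myl9 at 1.97 and Myh11 at 1.23 (camera, adjusted p = 0.00683, and adjusted p = 0.515 with an estimated correlation). Epithelial tumour cell markers had 0 higher, 1 lower and 8 not passing. Macrophage and granulocyte markers had 1 higher of 6, and 0 when adjusted over the list alone. In the smaller lists, 1 of 3 lymphatic markers was higher and 1 lower (Flt4, -1.64), 2 of 3 lymphocyte markers were higher, 1 of 3 adipocyte markers was higher and 2 lower, 2 of 2 erythroid genes were lower, the 1 Schwann cell marker Ngfr was higher (1.73) and 0 of 2 MHC class II genes passed.

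Of 23 interstitial matrix genes 21 were higher in wild-type pericytes, 22 adjusted over the list alone (camera, adjusted p = 1.55e-26, and adjusted p = 0.00926 with an estimated correlation). Basement membrane genes went both ways, 4 higher and 5 lower of 15, with the laminins Lama2 at 1.33 and Lamb2 at 1.08 and with Nid2 at -1.84 and Lama5 at -1.15. Of 21 matrix proteases and inhibitors 15 were higher and 2 lower, with Mmp3 at 3.90, the gelatinase Mmp2 at 3.30, Adamts2 at 3.13 and Timp1 at 2.91 (camera, adjusted p = 4.89e-08, and adjusted p = 0.0101 with an estimated correlation). Of 17 inflammatory cytokine genes 14 were higher, with the chemokines Ccl11 at 4.00, Ccl7 at 3.23 and Cxcl12 at 2.93 and the prostaglandin synthase Ptgs2 at 2.14 (camera, adjusted p = 1.01e-09, and adjusted p = 0.00669 with an estimated correlation). Of 16 angiogenic tip cell genes 13 were lower and 1 higher, with Trp53i11 at -2.99, Cxcr4 at -2.98 and Apln at -2.85 (camera, adjusted p = 1.01e-09, and adjusted p = 0.0101 with an estimated correlation). Of 16 endothelial junction genes 12 were lower, with Esam at -2.00 and Gja1 at -1.42 (camera, adjusted p = 4.94e-07, and adjusted p = 0.00669 with an estimated correlation). The TGF-beta and BMP list had 10 higher and 3 lower of 21, with Tgfbr3 at 1.36 and Id2 at 1.14 (camera, adjusted p = 0.00753, and adjusted p = 0.0244 with an estimated correlation).

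Cell cycle genes had 10 lower and 0 higher of 23, with Birc5 and Mcm6 both at -0.80 (camera, adjusted p = 0.00314, and adjusted p = 0.551 with an estimated correlation). Immediate early genes had 11 higher and 1 lower of 18, with Egr2 at 2.79 and Nr4a1 at 1.13 (camera, adjusted p = 8.45e-04, and adjusted p = 0.467 with an estimated correlation). Camera called none of the remaining lists or the basement membrane genes. Of these, fry, which tests whether a list moves on balance 1 way and compares it with no other genes, called Notch and arterial genes (adjusted p = 1.74e-05), PDGF and pericyte recruitment genes (adjusted p = 1.97e-08), leukocyte adhesion genes (adjusted p = 6.46e-08) and basement membrane genes (adjusted p = 0.00294). Notch and arterial genes had 4 higher and 8 lower of 14, with Notch3 at 1.57 and Notch4 at -2.94. PDGF and pericyte recruitment genes had 9 higher and 7 lower of 16, with Pdgfra at 3.57, the endothelin receptor Ednra at 2.78 and Angpt2 at -2.23. Leukocyte adhesion genes had 1 higher and 6 lower of 13, with Icam2 at -2.34 and Selp at -1.11. Hypoxia genes had 5 higher and 5 lower of 17, with Vegfa at 1.72 and the prolyl hydroxylase subunit P4ha2 at 1.25. Interferon response genes had 2 higher and 6 lower of 18, with Rsad2 at -1.47 and Ifit2 at -1.04. Heat shock genes had 3 higher and 2 lower of 12, with Dnajb1 at 0.54 and Hspb1 at -0.81. Oxidative phosphorylation genes had 3 lower of 35 and ribosomal protein genes 1 higher of 34. Endosialin ligands and C-type lectin relatives had 4 higher and 2 lower of 8, with Col1a2 at 3.69, Fn1 at 2.90 and Cd93 at -3.42, and the chromosome 19 neighbours of Cd248 had 3 higher and 9 lower of 31.

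In knockout all 25 endothelial markers were lower, 19 of 20 fibroblast markers and 21 of 23 interstitial matrix genes higher, 16 of 21 proteases higher and 2 lower, 15 of 16 tip cell genes lower, 13 of 16 junction genes lower and 1 higher, 14 of 17 cytokine genes higher and 12 of 21 TGF-beta and BMP genes higher and 3 lower. Examples are Mmp2 at 3.34, Cxcr4 at -3.04, Ccl7 at 3.78 and Cxcl12 at 3.09. These 8 lists held with an estimated correlation, with camera adjusted p between 1.95e-04 and 0.02. The other calls in knockout did not. Pericyte markers had 14 higher and 1 lower of 18, with Rgs4 at 2.02 (camera, adjusted p = 4.32e-07, and adjusted p = 0.284 with an estimated correlation), and smooth muscle genes had 6 higher and 1 lower of 10, with Tpm2 at 2.81 (camera, adjusted p = 0.00190, and adjusted p = 0.431 with an estimated correlation). Epithelial markers, of which 0 were higher in wild type, had 6 higher of 9, with Krt14 at 3.84 (camera, adjusted p = 9.48e-04, and adjusted p = 0.397 with an estimated correlation), and leukocyte adhesion genes 7 lower and 1 higher of 13 (camera, adjusted p = 0.0436, and adjusted p = 0.123 with an estimated correlation). Cell cycle genes had 10 lower of 23 (camera, adjusted p = 0.00753, and adjusted p = 0.565 with an estimated correlation) and immediate early genes 10 higher and 1 lower of 18 (camera, adjusted p = 0.00122, and adjusted p = 0.431 with an estimated correlation). Beyond these lists fry called Notch and arterial genes (adjusted p = 2.25e-05), PDGF and pericyte recruitment genes (adjusted p = 1.11e-07) and basement membrane genes (adjusted p = 3.62e-04) in knockout. The knockout count fell to 2075 with the keratinocyte mean as a covariate and to 2207 without knockout pericyte replicates 2 to 4.

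**Figure D4:**
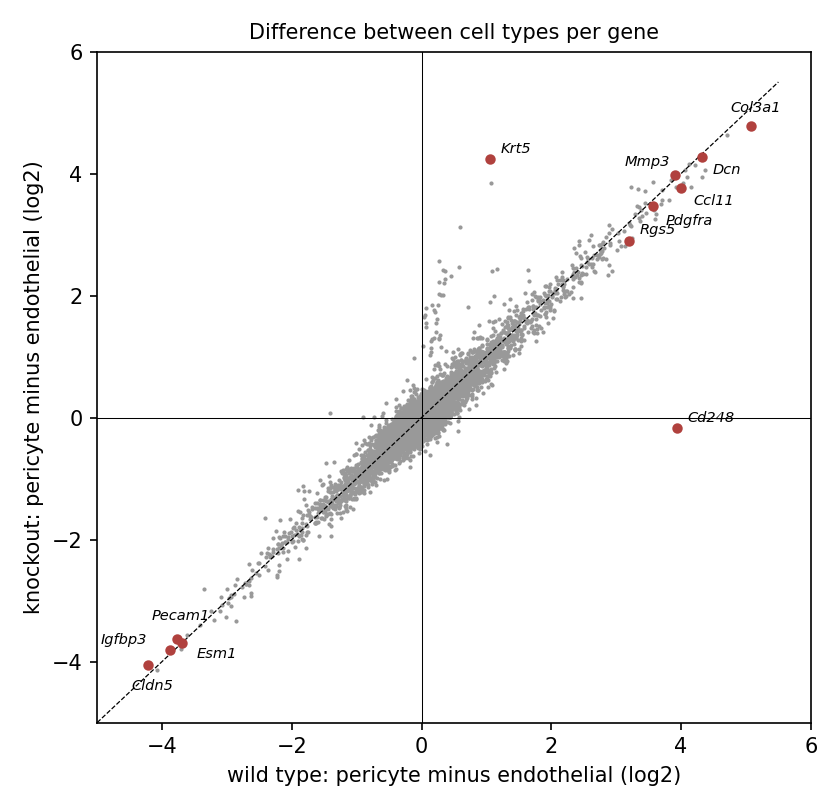
Each point is 1 of 10426 genes, with the log2 difference of pericytes minus endothelial cells in wild type on the horizontal axis and in knockout on the vertical axis, and the dashed line marks equal differences. Most genes lie along the line (r = 0.951 across genes), while Cd248 lies at 3.94 and -0.18 and Krt5 at 1.06 and 4.24.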

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

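The tests of other splits of the samples were set before the results were seen, and the tests on keratinocyte transcripts were chosen after.

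The keratinocyte-type transcripts that were higher in knockout pericytes came mainly from replicates 2, 3 and 4, where the list mean was 9.64, 9.55 and 9.19 against 7.41 in replicate 1, and Krt5 reached 12.06 in replicate 3. Skin keratinocytes or basal epithelial cells in the sort of some arrays may be the source, although a pericyte gate should remove such cells and its markers are not given. Without knockout replicate 1, the 8 list genes not called followed Krt5 and Krt14 in their deviations from group means over the other 7 pericyte arrays with a median r of 0.884 (0.79 for the 30 other genes called higher and 0.03 for all other genes), which transcripts varying together within the pericytes would give as well. Over all 8 arrays Sdc4 (r -0.30) and Osbp (r -0.24) did not follow Krt5 and Krt14. AW555464 (r 0.15) and the anchoring fibril collagen Col7a1 (r 0.27) followed them only weakly. Luminal-type epithelial cells stay open too, since Krt8 and Krt18 differed by a mean of 0.379 (SE 0.281) beside the list's median of 1.72 but are 2 genes near the floor in most arrays, and their mean lay above that of wild type by 1.61 in replicate 4 against 0.02 and 0.21 in replicates 2 and 3. Of the 21 list genes, 3 are also on the epithelial list and 1 lay above the array median on every wild-type pericyte array. A change in the pericytes themselves in every knockout sample stays open and cannot be told apart from this. Of the 13 list genes called, 4 had all knockout arrays above all wild-type arrays, and replicate 1 lay below the wild-type mean for 1 gene. The list mean of replicate 1, 7.41, lay below that of the highest wild-type pericyte array, 7.75.

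Other splits of the 8 pericyte arrays put this in context. Of 35 splits, 5 gave at least the 33 genes of the real one, so chance cannot be excluded, and the highest other split gave 325. That split set knockout replicate 1 with wild-type replicates 1 to 3 against wild-type replicate 4 with knockout replicates 2 to 4, which points to a structure of the samples other than genotype. In endothelial cells 7 of 35 splits gave at least the 1 gene of the real one, with 12 in the highest other, and for the difference of effects 12 of 100 drawn regroupings, which regrouped each cell type on its own, gave at least the 2 genes of the real one, with 30 in the highest other, so chance is not excluded for either count. For the cell type comparisons 1 of 35 splits, the real one, gave as many genes in wild type (3772, with 1 in the highest other). In knockout it was also 1 of 35 (3743, with 1 in the highest other). Both shares lie under 0.05, at the smallest that 35 splits can give. Every other split mixes the cell types, so its count was bound to be low.

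The knockout effect differed between the cell types in a direct test for Cd248 (-4.12) and LOC100042514 (1.38), and by list for the median of epithelial tumour cell markers (1.03) and of interstitial matrix genes (-0.14), where neither list holds with an estimated correlation.

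In 31 of 410 combinations of a named gene and a group, 1 array stood far from the other 3, where chance sets apart about 1 in 20 groups. Of these, 12 were in knockout pericyte replicate 1. There 9 genes called higher in knockout pericytes, 7 of them keratinocyte-list or stefin genes, were the lowest of their group: Stfa1 at 8.11 (others from 10.43), BC100530 at 7.69 (others from 9.64), BC117090 at 7.59 (others from 9.40), Krt6b at 7.16 (others from 9.90), Krt16 at 7.08 (others from 9.82), Krtdap at 7.26 (others from 9.44), Aqp3 at 7.22 (others from 9.50), 2310040C09Rik at 7.29 (others from 9.21) and C230053B09Rik at 8.41 (others from 8.60). The matrix and chemokine genes Bgn at 12.34, Col5a2 at 9.81 and Ccl11 at 11.01 were the highest of their group in that array, with the others up to 12.01, 9.47 and 10.61. In knockout pericyte replicate 4 Egfl7 was low at 6.82.

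In wild-type pericytes, replicate 4 was low for Col3a1 (11.52), Cxcl12 (9.02) and Egr2 (9.79) and high for Esm1 (7.05). Replicate 3 was high for Stfa3 (7.49), LOC100042514 (7.75) and Id2 (8.86). Replicate 2 was low for Tgfbi (6.82) and replicate 1 high for Usp18 (7.71). In wild-type endothelial cells, replicate 2 was high for Il11 (6.98), Nid2 (10.48) and Birc5 (8.60) and low for Gucy1a3 (6.81), replicate 1 was low for Kdr (7.31), replicate 3 high for Tgfbr3 (8.38) and replicate 4 high for Cd248 (7.33). In knockout endothelial cells, replicate 1 was high for Apln (11.18) and replicate 2 for Stat5a (7.95).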

How the results depend on the processing

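The alternatives with a keratinocyte covariate or without the 3 knockout pericyte arrays highest in keratinocyte transcripts were chosen after seeing the data. The loss of Cd248 in pericytes passed under every alternative run, from -3.99 with array weights to -2.86 as the mean of its probes, and its other probe, tested on its own, stood at -1.84. Of 6559 values of named genes under alternatives, 6069 kept their direction and side of the threshold, 455 no longer passed (428 of them in the pericyte knockout comparison), 24 newly passed and 11 reversed.

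The pericyte knockout count of 33 became 14 with no filter, 5 with a stricter filter, 1 with only the groups compared, 16 with a trended robust variance, 96 with array weights, 1 with the keratinocyte mean as a covariate and 1 without the 3 arrays. Leaving out 1 array each gave 3 to 130. The endothelial count of 1 became 2 with every kept probe tested, 2 with array weights and 0 with a size threshold of log2 1, and leaving out 1 array gave 1 to 2. The count for the difference of effects, 2, became 1 with no filter, 1 with a stricter filter, 10 with array weights, 1 with the covariate and 1 without the 3 arrays, and leaving out 1 array gave 1 to 53. Between cell types the wild-type count of 3772 became 2176 with a stricter filter and 920 with the size threshold (3392 to 3827 leaving out 1 array). The knockout count of 3743 became 2034, 954, 2075 with the covariate and 2207 without the 3 arrays (3348 to 3939 leaving out 1 array). The stricter filter tests 5683 genes and no filter 16537, the size threshold removes small differences by construction, and leaving out the 3 arrays leaves 1 knockout pericyte array, assumed to vary like the other groups. The 3 arrays were picked by their keratinocyte mean, so leaving them out lowers keratinocyte genes by construction. With only the groups compared the pericyte differences are the same by construction. The SE of the 32 higher genes rose there by a median factor of 1.31. For the remaining settings the cause was not tested.

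Camera called 4 lists in pericytes, 1 in endothelial cells, 2 for the difference of effects, 12 between cell types in wild type and 14 in knockout. With an estimated correlation these became 0, 0, 0, 8 and 8, and with fry 0, 0, 0, 16 and 17. With a replicate block camera gave 2 in endothelial cells, where macrophage and granulocyte markers came in, and 1 for the difference, and fry with a replicate block gave 0, 0 and 0 in the first 3. The cause was not tested.

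With the covariate, differences in pericytes turned to -0.043 for Aqp3, -0.072 for Dsp, -0.069 for Krt16, -0.23 for S100a9, -0.15 for Hbegf, -0.029 for Pkp4 and 0.030 for Col5a2. Aqp3, Dsp and Krt16 are themselves among the 21 genes of the covariate, which takes up part of their difference by construction. Without the 3 arrays differences turned to -0.038 for Krt16, -0.31 for S100a9, -0.18 for Hbegf and -0.059 for Pkp4. These arrays were picked by a mean that includes Krt16, which lowers its difference by construction. Beyond these constructions the cause was not tested. Osbp in pericytes stood at 0.68 under both, with a limma adjusted p of 0.387 and 0.340, against 0.404 with only the groups compared and 0.0523 without knockout pericyte replicate 3. Its difference in endothelial cells failed only the size threshold.

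Deviations of arrays that share a replicate number correlated between 0.04 and 0.43 across wild-type cell types, where the own number was the best match in 4 of 4, and between 0.03 and 0.22 in knockout (3 of 4), but between -0.08 and 0.45 across pericyte genotypes (1 of 4) and between -0.18 and 0.15 across endothelial genotypes (2 of 4). The highest value in each set was that of replicate 1. Across pericyte genotypes replicates 2, 3 and 4 lay at or below 0.02. Some pairs lie under 0.1 in each of these sets and the labels state no shared tumour, so the numbers were not used to pair samples. The best matches within a genotype are a hint from the data, and a tumour shared by a pericyte and an endothelial sample stays open. A replicate block as a fixed term gave 40 genes in pericytes, 32 of them among the 33, then 1, 2, 3871 and 3815, and a random block within genotype (correlation 0.135) gave 32, 1, 2, 4117 and 4066. The repository's own table holds the same values and tests nothing. A block for the chip was not run, since no chip is named. Signal over background limits dim genes: differences near the floor of the arrays are compressed.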

Other observations

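The 4 tests on chromosome 19 and on marker means below were chosen after the results were seen, and the mast cell list was written after the first calls.

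Mast cell and T cell transcripts were present in the pericyte sort of both genotypes. The mast cell protease Tpsab1 stood at 9.50 ± 2.07 in wild-type and 9.95 ± 1.55 in knockout pericytes, against 7.07 ± 0.24 and 7.06 ± 0.23 in endothelial cells (SD, n = 4 each). Cpa3 stood at 8.80 ± 1.82 and 8.95 ± 1.32, Cma1 at 8.47 ± 1.57 and 8.58 ± 1.19 and Mcpt4 at 8.32 ± 1.51 and 8.36 ± 1.09 in pericytes, with endothelial means of 6.73 to 6.87. Of 10 mast cell markers 6 were higher and 1 lower in pericytes in each genotype, with medians of 1.62 and 1.72, and none differed between knockout and wild-type pericytes. Their mean was uneven between arrays, at 7.07, 7.72, 9.26 and 9.86 in wild-type pericytes and 7.25, 8.83, 9.56 and 8.78 in knockout pericytes, against 7.35 to 7.48 in endothelial cells. Cd3e, a CD3 subunit of the T cell receptor complex, was higher in pericytes by 1.66 in wild type and 2.23 in knockout (limma, adjusted p = 1.26e-04 and 4.35e-06). With the keratinocyte mean as a covariate its knockout difference was 0.72 (limma, adjusted p = 0.0815). Cd8b was higher by 0.92 in both genotypes. The other tested lymphocyte marker, Cd2, was not among those higher in wild-type pericytes.

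Among the adipocyte markers lipoprotein lipase, Lpl, was 16.4-fold higher in wild-type pericytes (log2 difference 4.04), while the fatty acid carrier Fabp4, which capillary endothelium also expresses, fell by 2.21 there. Both haemoglobin transcripts were higher in the endothelial sort in wild type, and in knockout Hbb-b1 was higher (limma, adjusted p = 0.00757) while Hba-a1 did not pass (limma, adjusted p = 0.0715). Hbb-b1 stood at 8.66 ± 0.45 in wild-type and 8.17 ± 0.98 in knockout endothelial cells against 6.92 ± 0.07 and 6.98 ± 0.24 in pericytes, and Hba-a1 at 8.28 ± 0.46 and 7.62 ± 0.93 against 6.80 ± 0.04 and 6.87 ± 0.13 (SD, n = 4 each). Knockout endothelial replicates 2 and 3 read 6.85 and 6.99 for Hba-a1, within the range of the pericyte arrays, 6.75 to 7.05. The neutrophil list had 1 tested member, S100a9, which was higher in pericytes in knockout (1.74) and did not pass in wild type. The luminal list had 0 of 2 members passing in any comparison.

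Osbp lies on chromosome 19, as Cd248 does, and was higher in knockout arrays of both cell types. A chromosome 19 segment of other strain origin, carried along with the deleted gene, is a candidate explanation. Of the 100 tested genes nearest to Cd248, 12 (12%, 8 of them higher) had an unadjusted p under 0.05 for the knockout effect averaged over cell types. The share on other chromosomes was 6.86% (one-sided Fisher exact p = 0.0426, and 0.0202, 0.00625 and 0.0152 for the nearest 50, 200 and 285). The windows are nested, and the test takes genes of the same arrays as independent, so these p-values do not measure spread between samples. Chromosome 19 as a whole had the highest share of any, 10.8%, followed by chromosomes 3 and 4 with 8.9% and 8.4%. Osbp itself is the 123rd nearest, and 13 of 24 and 15 of 30 genes with such a p were higher in the 2 widest windows. The list of 31 neighbours fixed beforehand had 6 such genes (19.4%, 4 of them higher, one-sided Fisher exact p = 0.0176), but 0 members passed in pericytes or endothelial cells, and neither camera (adjusted p = 0.420 and 0.888) nor fry for changes in either direction (adjusted p = 0.221 and 0.987) called it, so the segment stays a hypothesis. Base differences under single probes remain open, as only 4 other kept probes of these genes exist. Of these, 3 had the direction of the main probe and 1, of Dpp3 at 0.23, had it with an unadjusted p under 0.05. Osbp, Kat5 and Cfl1 have 1 kept probe each, so no other probe checks them. Averaged over cell types, Osbp was higher by 0.64 (limma, adjusted p = 2.96e-05), Kat5 by 0.33 (limma, adjusted p = 0.0694, not passing) and Cfl1 by 0.79 (limma, adjusted p = 0.161, not passing). The genes that passed for this average were Cd248, Osbp, LOC100042514 and, on chromosome 5, Acads, which fell by 0.71 (limma, adjusted p = 0.0314). Of 8 genes whose arrays parted by genotype alike in both cell types, where chance gives 4.26, Osbp and Kat5 lie on chromosome 19 and Acads is among the others. An effect of the knockout on Osbp itself was not tested.

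Pericyte and fibroblast marker means moved in opposite directions across the 8 pericyte arrays, with a Pearson r of -0.80 (two-sided exact permutation p = 0.0167, adjusted 0.0251 over 3 relations) and a Spearman rho of -0.67 (exact permutation p = 0.0831). A difference in overall signal between arrays would move both means together, unlike the r of -0.80. The deposited values were already normalized, with array medians of 7.18 to 7.21, so this r cannot tell whether there was such a difference. Pericyte and fibroblast-like cells in varying shares of the sort may contribute, since deviations from group means had an r of -0.83 (permutation p = 0.0127). Such deviations are tied together within each genotype, so a permutation over all 8 arrays is not exact for them. The pericyte marker mean had an SD of 0.56 in wild-type and 0.12 in knockout pericytes, so the wild-type arrays weigh most. Without the 2 arrays farthest from the median, wild-type replicates 1 and 4, r was -0.71 over 6 arrays (exact permutation p = 0.158), of similar size and no longer past the threshold, so whether the relation rests on those arrays stays open. No biological explanation was tested.

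The other 2 relations of this family concern interstitial matrix genes. Pericyte markers and matrix genes had an r of -0.59 (exact permutation p = 0.129, adjusted 0.129) and a rho of -0.67 (exact permutation p = 0.0831), which did not pass, and without the 2 farthest arrays r was -0.72 (exact permutation p = 0.121). Fibroblast markers and matrix genes had an r of 0.93 (exact permutation p = 8.19e-04, adjusted 0.00246) and a rho of 1 (exact permutation p = 4.96e-05, the smallest they can give). Without the 2 farthest arrays, here wild-type replicates 2 and 4, r was 0.89 (exact permutation p = 0.0264).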
